A study of Homo sapiens with 12 samples.

How the data were processed

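RNA of MCF-7 cells, an estrogen receptor positive human breast cancer line, was measured on 12 one-colour Affymetrix gene arrays with biotin label. The cells had been transduced with lentiviruses carrying a hairpin RNA and were harvested 4 days later, after culture in medium whose serum had been charcoal-treated to remove retinoids, per the labels' protocols. The hairpin was directed against luciferase (shluc, the control, 6 arrays), HuR (shHuR, 3 arrays) or CRABP2 (shCRABP2, 3 arrays). Groups and array numbers were taken from the sample titles. Nothing in the labels says whether arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

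The deposited table held log2 signals of 53617 probe sets, made by the authors with RMA (background correction, quantile normalization and summarisation), Affymetrix Expression Console and Transcriptome Analysis Console, per the submitters' processing notes. Versions were not given in the sources used here, and no scanner files were used. The array medians fell into 2 sets. The arrays shluc 1 to 3 and shHuR 1 to 3 had medians from 4.43 to 4.46, and shluc 4 to 6 and shCRABP2 1 to 3 had medians from 5.11 to 5.16. Correlations of log2 signals over probe sets were 0.985 to 0.992 between arrays of a set and 0.956 to 0.968 between sets. The values were therefore taken as 2 tables normalized separately, split at the widest gap between the sorted medians, and each knockdown was tested only against the 3 shluc arrays of its own set. The labels do not say which shluc arrays belong to which of the series' experiments.

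This departs from the design written before the data were examined, in which all 6 shluc arrays were to be the control of both knockdowns. That pooled fit is given beside the results it changes. The choice of the set-wise fit was made after seeing the data, as were the use of all probe sets, the controls of the other set after quantile normalization, the correlation with genes left out, and 20 gene families picked by symbol prefix.

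Gene names came from the platform annotation in the table of probes and genes, in which 16098 probe sets had 1 gene symbol, 0 had several and 37519 (the rest) were unnamed here. All 16098 symbols were matched by gene ID to the gene table of assembly GRCh38.p14, which was used for names and gene types alone. For the 779 genes with more than 1 named probe set, the one with the highest mean log2 signal over the 12 arrays was used, which left 14884 genes. No filter on dim probe sets was applied. ELAVL1, the gene of HuR, has no named probe set here and was not analysed here, nor were CASP7, CASP9, BTG2, CDKN1A and RARA. For arrays, the number of arrays limits the precision, and the median SE of a log2 change was 0.105.

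One linear model with 4 group means (shHuR, shCRABP2 and the shluc arrays of each set) was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with 8 residual and 5.3 prior degrees of freedom. Its contrasts were shHuR minus shluc 1 to 3, shCRABP2 minus shluc 4 to 6, and the difference between these 2 effects. P-values were adjusted by the Benjamini-Hochberg method over 14884 genes with a threshold of 0.05, and "rose" and "fell" are used of genes past it. Gene lists were fixed before the data were examined. Of 21 lists, the 20 with at least 3 measured genes were tested with camera at its preset correlation of 0.01, adjusted over the 20 lists of a comparison, with camera at an estimated correlation and with fry as alternatives. The list of replication-dependent histones had 0 measured genes.

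Genes named in the text follow a rule written before the data were examined. It takes CRABP2, the 10 highest and 10 lowest log2 changes among genes past the threshold whose knockdown arrays all lie beyond the shluc arrays, up to 4 genes of each list with the smallest adjusted p, 5 genes risen and 5 fallen in both comparisons with the largest smaller change, and APAF1, CCND1, FABP5, PPARD and MYC. The rule asked for knockdown arrays beyond all 6 shluc arrays and was applied to the 3 of the same set. MicroRNA genes, pseudogenes and genes without a real name kept their rank and were only counted.

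The fit was tested on simulated data for each comparison, with 200 of 14884 genes changed. The other genes of the G2/M and mitosis list were shifted by -0.3 log2 and not counted as false calls. For shHuR against shluc it recovered 84% of the genes changed 1.5-fold and 100% of those changed 2-fold, with 4.15% false calls. For shCRABP2 against shluc it recovered 78% and 100%, with 4.74% false calls. The simulated noise was independent between genes. In the data the estimated correlation was 0.28 for the S phase list and 0.45 for the G2/M list. The shares of false calls therefore need not carry over to these arrays. Alternatives covered the control arrays, the arrays in the fit, the spread model, the normalization, a filter on dim genes, the probe sets, array weights, a fold threshold of 1.5, the replicate number as a block and each array left out. Leaving the other set's shluc arrays out of the fit kept each contrast within a set and changed only the estimate of spread.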

Results

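The series compared gene expression in MCF-7 breast cancer cells after knockdown of HuR or of CRABP2 with cells carrying a hairpin against luciferase, all without retinoic acid. HuR, encoded by ELAVL1, is an RNA-binding protein that stabilises many AU-rich transcripts. CRABP2 carries retinoic acid to its nuclear receptor, and the study asked what it does in the absence of that ligand, as the pair of knockdowns implies. Log2 signals of 14884 genes were compared on 12 arrays, 3 for shHuR, 3 for shCRABP2 and 6 for shluc. The arrays formed 2 separately normalized sets, so shHuR was set against shluc 1 to 3 and shCRABP2 against shluc 4 to 6, and levels are not comparable across the sets.

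The knocked-down genes were examined first. CRABP2 had log2 signals of 8.92, 8.90 and 8.94 on the shCRABP2 arrays and of 9.90, 10.40 and 10.08 on shluc 4 to 6. It was 2.31-fold lower in shCRABP2 cells, a log2 change of -1.21 ± 0.11 (SE, n = 3 arrays per group, limma adjusted p = 0.00035). In shHuR cells it measured 9.16, 9.13 and 9.20 against 8.97, 9.21 and 9.09 on shluc 1 to 3, a log2 difference of 0.07 ± 0.11 that did not pass the threshold (adjusted p = 0.78). ELAVL1 was not analysed here under its name, so the shHuR label was not checked on its own target.

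**Figure D1:**
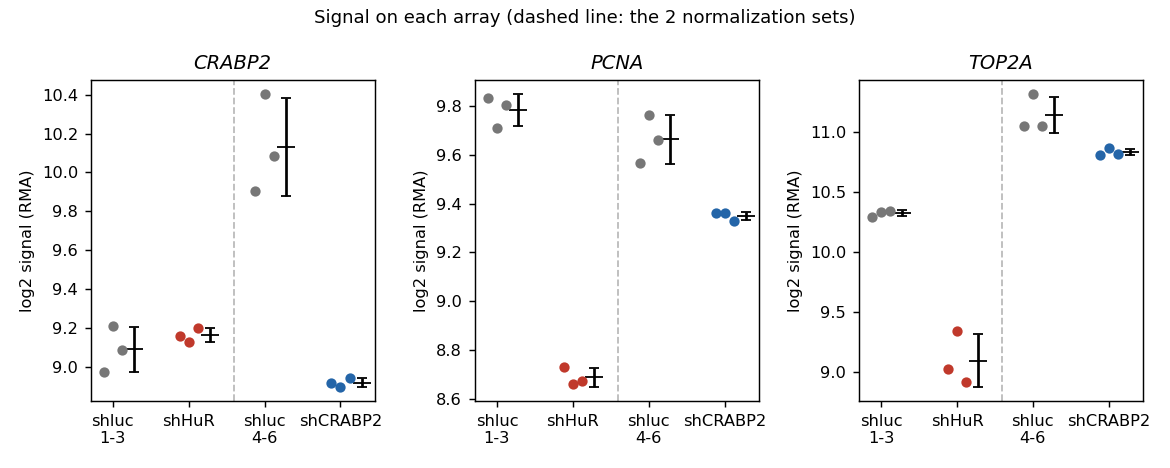
Log2 signal (RMA, y axis) of CRABP2, PCNA and TOP2A on each array, by group (x axis), where points are arrays, the bar beside them is the mean ± SD (n = 3) and the dashed line parts the 2 separately normalized sets. CRABP2 is lower on the 3 shCRABP2 arrays than on shluc 4 to 6, and PCNA and TOP2A are lower on the 3 shHuR arrays than on shluc 1 to 3.

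Genes of DNA replication and cell division were lower in shHuR cells. Of the 27 measured genes of S phase and DNA replication, 26 fell, with a median log2 change of -0.95, and adjusted over the list alone 27 fell. MCM10, a replication initiation factor, was 2.43-fold lower (log2 change -1.28 ± 0.08, SE, n = 3 arrays per group). PCNA, the sliding clamp of DNA polymerases, was 2.14-fold lower, GINS2 of the replicative helicase was 2.43-fold lower and the helicase subunit MCM5 was 2.32-fold lower. Of the 26 genes of G2/M and mitosis, 24 fell, with a median log2 change of -0.74, and adjusted over the list alone 26 fell. TOP2A, DNA topoisomerase II alpha, was 2.34-fold lower, the spindle checkpoint kinase BUB1 2.07-fold lower, cyclin A2 (CCNA2) 2.03-fold lower and the mitotic kinase CDK1 1.90-fold lower. The exceptions, named after their values were seen, were SLBP at -0.25 (adjusted p = 0.16), HMMR at -0.58 (adjusted p = 0.052) and CKAP2 at -0.31 (adjusted p = 0.067). Both lists shifted against the other genes in the camera test (adjusted p = 4.32e-43 and 5.87e-34), and both stayed past the threshold with an estimated correlation (adjusted p = 0.012 and 0.042). The mean of the S phase list lay between -0.96 and -0.83 on the 3 shHuR arrays, relative to shluc 1 to 3, while the mean of the luminal epithelial list lay between -0.01 and 0.02 and that of the basal and mesenchymal list between 0.15 and 0.25.

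Within the S phase list, E2F1, a transcription factor of the G1/S transition, was at -1.15 ± 0.13 (SE) in shHuR cells. Outside the S phase and G2/M lists, the genes with the lowest log2 changes in shHuR cells were ZNF732 at -1.47 ± 0.12, RAD54L, a recombination repair factor, at -1.36 ± 0.10, ZNF367 at -1.26 ± 0.13, SHCBP1 at -1.13 ± 0.13 and C18orf54 at -1.11 ± 0.11. The highest were BNIPL at 1.67 ± 0.17, KLHL4 at 1.28 ± 0.15, ANKRD22 at 1.25 ± 0.13, PBXIP1 at 1.20 ± 0.14 and the growth factor FGF18 at 1.20 ± 0.15. GRAMD1C at 1.16 ± 0.13, GPX8 at 1.12 ± 0.13, TMT1A at 1.09 ± 0.11 and the uroplakin UPK1A at 1.05 ± 0.10 followed, and 1 microRNA gene also ranked among the 10 highest. The adjusted p of each of these genes was 0.00025 or lower.

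Among the transcripts known as HuR targets from other systems, 4 of 25 fell and 1 rose. Cyclins made up the fall, with CCNA2 at -1.02 ± 0.09 (SE), cyclin E1 (CCNE1) at -0.66 ± 0.08 and cyclin D1 (CCND1) at -0.68 ± 0.09. The remaining gene that fell was CCNB1. CCNA2 and CCNB1 also belong to the G2/M list and CCNE1 to the S phase list, so their fall is not separate from that of those lists. Of the genes that fell, CCND1 alone lay outside them. FOS rose by 0.61 ± 0.12. The list as a whole did not shift (camera adjusted p = 0.36), and adjusted over the list alone 6 fell and 1 rose. APAF1, which forms the apoptosome, had a log2 change of -0.31 ± 0.10 that missed the threshold (adjusted p = 0.059), passed it after a further quantile normalization (adjusted p = 0.047), with array weights (0.030), without the dimmer genes (0.017) and without shHuR 2 (0.015). FABP5 at -0.18 ± 0.14, PPARD at 0.08 ± 0.09 and MYC at 0.10 ± 0.10 did not pass.

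Several smaller groups held genes that rose in shHuR cells. Of 17 basal and mesenchymal markers 5 rose, among them fibronectin (FN1) by 0.62 ± 0.08 (SE), the filament protein VIM by 0.86 ± 0.13, SNAI2 by 0.52 ± 0.11 and MSN by 0.49 ± 0.11. That list shifted up (camera adjusted p = 0.026), a call lost with an estimated correlation (adjusted p = 0.33), without shluc 2 (adjusted p = 0.097) and without shHuR 3 (adjusted p = 0.095). The other probe sets of VIM gave 0.02 and 0.54. Of 17 p53 targets 4 rose, CCNG1 by 0.39 ± 0.09, SESN1 by 0.38 ± 0.09, EDA2R by 0.48 ± 0.12 and RRM2B by 0.34 ± 0.10, and the list did not pass against the other genes in camera, at the preset correlation (adjusted p = 0.14) or an estimated one (adjusted p = 0.52). It passed in fry (adjusted p = 0.022), which tests the list against no change and not against other genes. RRM2B lost its call in a fit of the 2 groups alone (limma adjusted p = 0.15), as did SESN1 (0.058) and EDA2R (0.0996). RRM2B also lost it with the shluc arrays of its set as the only controls (0.082), after median centring (0.062) and with array weights (0.092). Of 17 genes of the integrated stress and unfolded protein response 4 rose, namely DDIT4 by 0.76 ± 0.09, CTH by 0.83 ± 0.14, PSAT1 by 0.62 ± 0.13 and VLDLR by 0.36 ± 0.08 (list adjusted p = 0.19). VLDLR lost its call in the fit of the 2 groups alone (limma adjusted p = 0.061). Of 10 retinoic acid receptor targets 2 rose, the retinol dehydrogenase RDH10 by 0.61 ± 0.09 and the retinol transporter gene STRA6 by 0.57 ± 0.09. The same 2 genes were the ones that rose among 7 genes of retinoid transport and metabolism. Neither list passed (adjusted p = 0.28 and 0.36), and the list of retinoid transport, at a mean of 0.32 in place of 0.09, passed without the dimmer genes (adjusted p = 0.045).

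The remaining lists did not pass in shHuR cells, with camera adjusted p of 0.15 or higher. Without shluc 3, blood cell markers passed at a mean of 0.21 and small nucleolar RNAs at a mean of -0.20 (adjusted p = 0.037 for each). Of 23 estrogen response genes 4 rose, among them CXCL12 by 0.59 ± 0.07 (SE), and 3 fell, MYBL1 by 0.96 ± 0.10, AGR2 by 0.60 ± 0.08 and CCND1. Of 19 luminal epithelial genes TFAP2C rose by 0.36 ± 0.08 and PRLR by 0.33 ± 0.08, and in a fit of the 6 arrays alone neither passed (adjusted p = 0.057 and 0.082). Of 27 interferon response genes SAMD9 rose by 1.04 ± 0.15 and IRF9 by 0.49 ± 0.12. Of 17 hypoxia and glycolysis genes 3 rose, DDIT4, NDRG1 by 0.46 ± 0.08 and KDM3A by 0.30 ± 0.08, and 2 fell, among them EGLN3 at -0.31 ± 0.07. Of 20 immediate early genes FOS and IER3 rose, IER3 by 0.42 ± 0.11 on a probe set whose duplicates gave 0.19 to 0.42, while EGR1 was at -0.75 ± 0.11 on one probe set and at 0.21 on another. TMEM97 alone fell among 17 cholesterol synthesis genes, by 0.46 ± 0.10. BIRC2 alone rose among 19 apoptosis genes, by 0.26 ± 0.07, IGF2BP1 alone among 11 regulators of AU-rich transcripts, by 0.42 ± 0.10, and LCP1 alone among 9 blood cell markers, by 0.38 ± 0.10. BIRC2 lost its call with shluc 4 to 6 left out of the fit (adjusted p = 0.074) and in the fit of the 6 arrays alone (0.14). It also lost it after median centring (0.068), with array weights (0.060), with the replicate block (0.073) and with any 1 array left out. In the fit of the 6 arrays alone LCP1 (0.074), EGLN3 (0.068), KDM3A (0.095) and IER3 (0.081) lost their calls too. KDM3A also lost its call with shluc 4 to 6 left out of the fit (0.052), and PRLR with array weights (0.051). No gene passed among 10 PPAR targets, 23 small nucleolar RNAs and 49 ribosomal protein genes. Some genes passed only in alternatives. Without the dimmer genes these were SPDEF (adjusted p = 0.032), ACAT2 (0.016), NSDHL (0.022), EBP (0.029), BCL2L11 (0.019) and RPL30 (0.028). With trend and robust eBayes they were SPDEF (0.043), ACAT2 (0.036), NSDHL (0.027) and EBP (0.036), and after a further quantile normalization NSDHL (0.034) and BCL2L11 (0.045). With shluc 4 to 6 left out of the fit RPL39L passed (0.038). With an array left out, HOXB4 passed without shluc 1 (0.021) or shHuR 1 (0.047), SCARNA23 without shluc 3 (0.026), and XIAP (0.045), SCARNA8 (0.040) and RPL30 (0.047) without shHuR 3. Median, mean and direction of the test differed in sign for retinoic acid receptor targets (median -0.01, mean 0.12, up), retinoid transport (-0.01, 0.09, up), estrogen response (0.00, -0.02, down), luminal genes (-0.02, 0.01, up), cholesterol synthesis (0.02, -0.06, down), immediate early genes (-0.03, 0.00, up) and the regulators of AU-rich transcripts (-0.05, 0.02, up). Adjusted over the list alone, counts differed for p53 targets (7 rose, 1 fell), apoptosis (1 rose, 2 fell), retinoic acid receptor targets (3 rose), stress response (5 rose, 4 fell), estrogen response (5 rose, 4 fell) and cholesterol synthesis (1 rose, 5 fell).

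**Figure D2:**
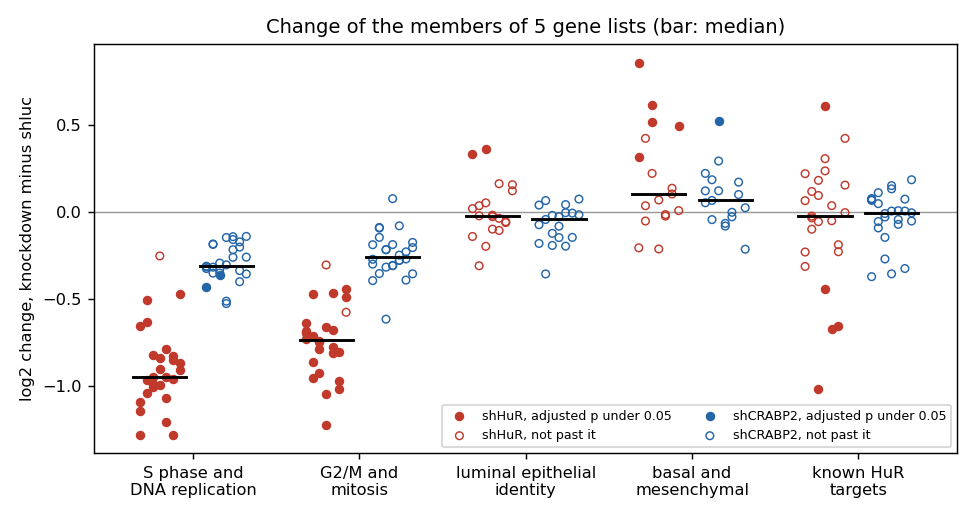
Log2 change (knockdown minus the shluc arrays of its set, y axis) of each measured gene of 5 gene lists (x axis) in shHuR (red) and shCRABP2 (blue), where a filled point is past an adjusted p of 0.05, an open one is not, and the black bar is the median. The S phase and the G2/M lists lie below 0 in shHuR, with medians of -0.95 and -0.74, and closer to 0 in shCRABP2, with medians of -0.31 and -0.26.

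Over all genes, 1408 passed the threshold in shHuR against shluc, 614 up and 794 down, of which 354 changed at least 1.5-fold, 100 up and 254 down. Of the 1408, 99.3% had 3 shHuR arrays wholly above or below the 3 shluc arrays. The threshold itself selects such genes, so this share is no separate support. Of all genes 24.5% were parted in this way, where chance gives 10%. A fit of the 6 arrays alone called 764, and the pooled fit to all 6 shluc arrays, in which the median gene shifted by -0.27, called 433, 44 up and 389 down. Of the 64 named genes past the threshold, 51 kept their call with each array left out in turn, and those that lost it at least once were BIRC2, CCNG1, SESN1, EDA2R, RRM2B, IRF9, PRLR, LCP1, VLDLR, EGLN3, KDM3A, IER3 and IGF2BP1, with adjusted p up to 0.17.

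Knockdown of CRABP2 was followed by fewer calls, mostly of lower expression. Besides CRABP2, the lowest log2 changes were those of the lysosomal thioesterase PPT1 at -1.23 ± 0.11 (SE, n = 3 arrays per group), 2.34-fold lower, the xylosyltransferase GXYLT2 at -0.90 ± 0.11, the transcription factor MYB at -0.81 ± 0.11, the mitochondrial glycerol-3-phosphate dehydrogenase GPD2 at -0.81 ± 0.08 and the tumour suppressor NF2 at -0.81 ± 0.09. SERTAD4 at -0.75 ± 0.13, the metallothionein MT2A at -0.75 ± 0.11 and SNX7 at -0.71 ± 0.12 followed. The highest were UPK3A at 0.75 ± 0.14, the long noncoding RNA PCGEM1 at 0.73 ± 0.11, NELL2 at 0.61 ± 0.11, LAPTM5 at 0.61 ± 0.12, the metalloproteinase MMP16 at 0.58 ± 0.11, SFT2D2 at 0.55 ± 0.08, CREBRF at 0.55 ± 0.09 and PIERCE2 at 0.55 ± 0.11, with adjusted p from 0.0105 to 0.0464. A second probe set of NELL2 gave -0.08. In a fit of the 2 groups alone MYB (limma adjusted p = 0.053), MT2A (0.058) and SFT2D2 (0.053) lost their calls. NELL2 (0.097), LAPTM5 (0.12) and MMP16 (0.096) lost theirs in that fit too. Among the 10 highest and the 10 lowest, 2 and 1 were microRNA genes and were only counted.

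The medians of the 2 cell cycle lists were also below 0 in shCRABP2 cells, by less than in shHuR cells, and few of their genes passed the threshold. Of the 27 S phase genes 2 fell, MCM10 by 0.43 ± 0.08 (SE) and the ribonucleotide reductase subunit RRM2 by 0.37 ± 0.07, and the median of the list was -0.31. Both genes lost the call with shluc 1 to 3 left out of the fit (adjusted p = 0.062 and 0.071). They also lost it in a fit of the 6 arrays alone (0.096 and 0.12) and with any 1 array left out. Adjusted over the list alone 19 fell. None of the 26 G2/M genes passed, with BIRC5 at -0.62 ± 0.13 (adjusted p = 0.052) and FOXM1 at -0.39 ± 0.09 (adjusted p = 0.082), a list median of -0.26 and 12 lower when adjusted over the list alone. BIRC5 passed with trend and robust eBayes (adjusted p = 0.0093), a further quantile normalization (0.046), median centring (0.049), array weights (0.042) and without the dimmer genes (0.0085). FOXM1 passed with trend and robust eBayes (0.016), array weights (0.035) and without the dimmer genes (0.016). CDC45 passed in the same 3 fits (adjusted p = 0.018 to 0.046), GINS2 with trend and robust eBayes (0.020) and without the dimmer genes (0.019), and CCNB1 without the dimmer genes (0.045). Camera placed both lists past the threshold (adjusted p = 1.85e-20 and 2.00e-13), but with an estimated correlation neither was (adjusted p = 0.11 and 0.39).

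Further lists were past the threshold in shCRABP2 only at the preset correlation. Cholesterol synthesis genes shifted down (camera adjusted p = 0.0066), with ACAT2 alone past the threshold at -0.44 ± 0.08 (SE) of 17 and INSIG1 at 0.36 ± 0.08 (adjusted p = 0.074). ACAT2 lost its call with shluc 1 to 3 left out of the fit (adjusted p = 0.054), in a fit of the 6 arrays alone (0.096) and with any 1 array left out. Interferon response genes shifted up (adjusted p = 0.0094) with 0 of 27 past the threshold and IRF9 at 0.53 ± 0.12. Stress response genes shifted up (adjusted p = 0.026) with 0 of 17 past it and ASNS at 0.38 ± 0.10, and basal and mesenchymal markers shifted up (adjusted p = 0.041) with FN1 alone of 17, up by 0.52 ± 0.08. INSIG1 passed with trend and robust eBayes (adjusted p = 0.012), a further quantile normalization (0.030), array weights (0.037) and without the dimmer genes (0.014), IRF9 with trend and robust eBayes (0.027) and without the dimmer genes (0.022), and ASNS (0.036) and EBP (0.045) without the dimmer genes. With an estimated correlation the adjusted p was 0.39 for cholesterol, interferon and mesenchymal genes and 0.46 for stress response genes. Without single arrays the interferon list (without shluc 5, adjusted p = 0.25, or shCRABP2 1, 0.11), the stress list (without shluc 4, 0.17, or shCRABP2 3, 0.076) and the mesenchymal list (without shluc 4, 0.091, shluc 5, 0.0504, shluc 6, 0.059, or shCRABP2 3, 0.20) lost the call. The mesenchymal list also lost it after a further quantile normalization (0.11) and with array weights (0.072).

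The other lists did not pass in shCRABP2 cells, with camera adjusted p of 0.14 or higher. Without shluc 4, luminal genes passed at a mean of -0.14 in place of -0.07 (adjusted p = 0.0038) and ribosomal protein genes at a mean of -0.11 (adjusted p = 0.025), while without shluc 5 the luminal mean was 0.02 (adjusted p = 0.83). MYB alone passed among 23 estrogen response genes. CA12 at -0.39 and CXCL12 at 0.31 (adjusted p = 0.086 for each) passed in 4 alternatives, namely trend and robust eBayes, a further quantile normalization, array weights and without the dimmer genes (adjusted p = 0.017 to 0.041 and 0.016 to 0.027). No gene passed among 25 known HuR targets (list adjusted p = 0.48), where APAF1 was at -0.37 ± 0.10 (SE, adjusted p = 0.14) and CCNE1 at -0.33 ± 0.08 (adjusted p = 0.13), nor among 19 apoptosis genes, 17 p53 targets, 10 retinoic acid receptor targets, 7 genes of retinoid transport, 10 PPAR targets, 19 luminal epithelial genes, 9 blood cell markers, 17 hypoxia genes, 20 immediate early genes, 11 regulators of AU-rich transcripts, 23 small nucleolar RNAs and 49 ribosomal protein genes. Without the dimmer genes APAF1 passed (adjusted p = 0.034), as did CCNE1 (0.032), which also passed with trend and robust eBayes (0.046). The p53 target PLK2 at -0.39 (adjusted p = 0.080) passed in the same 4 alternatives as CA12 (adjusted p = 0.015 to 0.046), and ACER2 without the dimmer genes (0.040). EDA2R passed with shluc 1 to 3 left out of the fit (0.0499). IGF2BP1 at -0.50 (adjusted p = 0.051) passed with trend and robust eBayes (0.037), a further quantile normalization (0.036), array weights (0.020) and without shluc 4 (0.020). Median, mean and direction of the test differed in sign for retinoid transport (median 0.02, mean -0.01, down), hypoxia genes (-0.01, -0.01, up) and small nucleolar RNAs (0.00, 0.01, up). CCND1 at -0.07 ± 0.09, FABP5 at -0.19 ± 0.14, PPARD at 0.06 ± 0.09 and MYC at -0.01 ± 0.10 did not pass. Adjusted over the list alone, counts differed for known HuR targets (3 fell), apoptosis (1 rose, 2 fell), p53 targets (3 rose, 2 fell), interferon (1 rose), stress response (1 rose), estrogen response (2 rose, 4 fell), cholesterol synthesis (1 rose, 4 fell) and the regulators of AU-rich transcripts (1 fell).

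Over all genes, 74 passed in shCRABP2 against shluc, 21 up and 53 down, of which 29 changed at least 1.5-fold, 5 up and 24 down. All 74 had shCRABP2 arrays wholly above or below shluc 4 to 6, which the threshold itself favours. Of all genes 18.8% were parted in this way, where chance gives 10%. The count was 21 in a fit of the 6 arrays alone and 0 in the pooled fit to all 6 shluc arrays, where 2172 genes had an unadjusted p under 0.05 and the CRABP2 change of -0.69 missed the threshold (adjusted p = 0.30). It was 49 without shluc 4, 9 without shluc 5, 14 without shluc 6, and 12, 11 and 7 without shCRABP2 1, 2 and 3, and CRABP2, PPT1, GXYLT2, GPD2 and NF2 were the 5 of 25 named genes that kept their call each time.

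The 2 effects were tested against each other, as the question of what CRABP2 and HuR share implies. The difference passed for 250 genes, 113 with a higher and 137 with a lower log2 change in shHuR. Each knockdown was measured in its own set alone. A difference in how the cells of the 2 sets respond, or in knockdown strength, therefore cannot be told apart from one between the targets. The log2 change of MCM10 was lower in shHuR, with a difference of -0.85 ± 0.11 (SE, limma adjusted p = 0.0052). Differences were -0.78 ± 0.11 for PCNA (adjusted p = 0.0059), -0.92 ± 0.15 for TOP2A (adjusted p = 0.013) and -0.60 ± 0.13 for CCND1 (adjusted p = 0.035). For CRABP2 the difference was 1.28 ± 0.16 and for PPT1 1.29 ± 0.15. Of the S phase genes 15 of 27 fell further in shHuR (median difference -0.68, 22 adjusted over the list alone), and of the G2/M genes 8 of 26 (median difference -0.47, 20 adjusted over the list alone). The S phase shift passed in camera (adjusted p = 4.93e-31) and with an estimated correlation (adjusted p = 0.033), the G2/M shift in camera (adjusted p = 4.34e-22) but not with an estimated correlation (adjusted p = 0.13). No other list passed in camera for the difference with all arrays. Without shluc 4, luminal genes (mean 0.15) and ribosomal protein genes (mean 0.14) passed (adjusted p = 0.036 for each), and without shluc 3 small nucleolar RNAs did (mean -0.21, adjusted p = 0.044). Median, mean and direction of the test differed in sign for known HuR targets, PPAR targets and stress response genes. For APAF1 the difference was 0.06 ± 0.14, with a 95% interval from -0.23 to 0.35. The count of 250 was 140 without shluc 2, 158 without shluc 3, 125, 132 and 105 without shluc 4, 5 and 6, 69 without shHuR 1, 141 without shHuR 3, and 52, 83 and 121 without shCRABP2 1, 2 and 3.

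Part of the response went the same way in both knockdowns. PCGEM1, CREBRF, PIERCE2, FN1 and TCP11L2 were the 5 named genes that rose in both, PIERCE2 by 0.98 ± 0.11 (SE) in shHuR and 0.55 ± 0.11 in shCRABP2 and FN1 by 0.62 ± 0.08 and 0.52 ± 0.08. SERTAD4, the cell cycle phosphatase CDC25A, SHCBP1, GXYLT2 and TMEM38B fell in both, CDC25A by 0.93 ± 0.11 and 0.68 ± 0.11. Of these named genes GXYLT2 alone kept its shCRABP2 call with each array left out in turn. In shCRABP2, PIERCE2 lost its call after median centring (limma adjusted p = 0.063) and SHCBP1 with shluc 1 to 3 left out of the fit (0.070). In a fit of the 6 arrays of that set alone PCGEM1 (0.055), CREBRF (0.087) and TCP11L2 (0.060) lost theirs. In all, 11 genes rose in both, where independent lists would share 0.87, and 21 fell in both, where they would share 2.83. One gene, ANXA1, named after its values were seen, rose in shHuR by 0.87 ± 0.08 and fell in shCRABP2 by 0.39 ± 0.08. Of the 74 genes called in shCRABP2, 68.9% had the same sign in shHuR, and of the 1408 called in shHuR 75.1% had the same sign in shCRABP2. Across genes, which are not independent replicates, the 2 log2 changes correlated with Pearson r = 0.27 and Spearman rho = 0.22 (covariance 0.0092), with no shluc array in common. Of 200 relabellings of the arrays within the sets, 1, the real one, gave an r as high (one-sided permutation p = 0.005, the smallest they can give). Both sets were relabelled at once, so this p-value refers to no effect in either set. It does not test whether 2 real effects are unrelated. With the 6 shluc arrays pooled, r was -0.44 and the covariance -0.036. Simulated unchanged groups set against 6 shared simulated controls gave 0.33 and 0.0035. The simulation held no difference between the sets, so it is no reference for the pooled values.

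**Figure D3:**
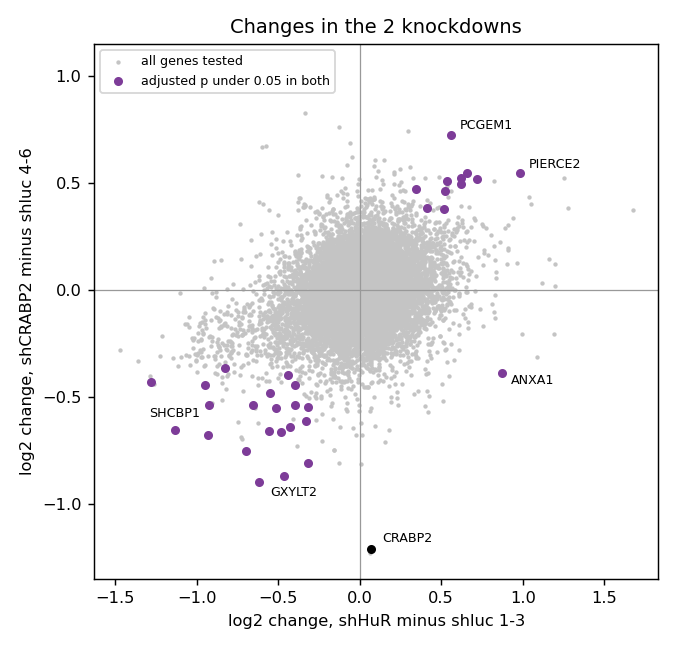
Log2 change of each of 14884 genes in shHuR (minus shluc 1 to 3, x axis) and in shCRABP2 (minus shluc 4 to 6, y axis), with genes past an adjusted p of 0.05 in both in purple and CRABP2 in black. Of the purple genes 11 lie above 0 and 21 below 0 on both axes, and ANXA1 has opposite signs.

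The control arrays were compared with each other as a check for a technical batch. Between shluc 4 to 6 and shluc 1 to 3, 11372 genes differed, 10866 of them higher in shluc 4 to 6, with a median shift of 0.55. After quantile normalization of all arrays, which left a median shift of -0.04, 7724 differed, 3433 higher and 4291 lower. With each array centred on the median of its probe sets, which left a median shift of -0.14 over genes, 8054 differed, 2611 higher and 5443 lower. Knockdowns could therefore be compared within their sets alone, and a level of CRABP2 in shluc 1 to 3 cannot be set against one in shluc 4 to 6.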

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

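The tests of other cell types, of a double-stranded RNA response, of off-target effects, of relabelled arrays and of left-out genes for the shared response were chosen only after the result was seen, and the other tests were written before their own values were seen.

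Probe sets without a gene name here were outside the comparisons of named genes. Of 37519, 657 passed the threshold in shHuR against shluc, 271 up and 386 down, and 7 passed in shCRABP2 against shluc, 2 up and 5 down. In shHuR, probe set 16934610 was at a log2 change of 2.37 ± 0.53 (SE, limma adjusted p = 0.040). Its mean on shluc 1 to 3 was 3.04, below the lower quartile of each of these arrays (3.19 to 3.25). Probe set 16761269 was at 1.97, and 16841575 and 17104519 were both at -1.73. In shCRABP2, 16811684 was at 1.11 and 16731269 at 0.74, and 16966026 and 16677556 were at -0.70 and -0.69.

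Among 150 named genes, 5 had 1 shluc array apart from the other 5 after each array was centred on its median, where chance gives about 1 in 20. The gap over the range was 0.645 for UPK1A (shluc 4), 0.671 for TOP2A (shluc 5), 0.719 for C18orf54 (shluc 3), 0.670 for PDPK1 (shluc 4) and 0.730 for SPDEF (shluc 4).

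The fall of S phase and mitosis genes in shHuR is the first pattern weighed. Cells of another type in place of MCF-7 cells would have lowered luminal genes by a like amount, but the lowest luminal list mean on a shHuR array was -0.0072. A double-stranded RNA response would have raised interferon genes together, but the upper quartile of that list was 0.12. An off-target effect of the hairpin cannot be told apart from the loss of HuR, since the labels give 1 construct name and the target was not analysed here. Of the 10 splits of the 6 arrays, 1, the real one, gave 1408 genes and the highest other 0, which is too few splits for a share under 0.05; slower division after loss of HuR stays a hypothesis.

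The shared part of the response is the second pattern. Relabelling the arrays within the sets gave an r as high as 0.27 in 1 of 200 cases, the real one, with 0.23 the highest other. Counting either sign, 2 of 200 were as large, the real labelling and its mirror. The test was chosen after r was seen, and arrays of a group may be technical repeats. It therefore speaks only to the labelling of these arrays and does not exclude chance between cultures. Because both sets were relabelled at once, most relabellings also removed the shHuR effect. They are thus no reference for 2 effects that are real but unrelated. Without the S phase and mitosis lists r was 0.26, and without them and every gene past the threshold it was 0.14. The bound for the second value, 0.1, was written after r but before that value was seen, and the value lay above it by less than 0.061, the jackknife SE of r over arrays, a margin added after the value was seen. Whether cell cycle genes alone carry the shared part stays open, and a response to any effective hairpin, as against one to the 2 targets, was not tested.

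The difference between shluc 1 to 3 and 4 to 6 is the third pattern. Separate normalization alone was taken to predict fewer than 100 differing genes after quantile normalization of all arrays, but 7724 differed, with 0 the highest of the other splits. That step matches the distributions of summarised values and cannot undo offsets of single probe sets from separate summarisation. The count therefore speaks only against a difference in distribution as the sole source. Of the 10 splits of the 6 shluc arrays, 1, the real one, gave 11372 genes and the highest other 0, too few splits for a share under 0.05. Separate processing and a batch of cells, RNA or hybridization stay open, and no biological explanation was tested, since the design names none.

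For shCRABP2, 1 of 10 splits, the real one, gave 74 genes and the highest other 0, too few splits for a share under 0.05. For the difference between the effects, 6 of 100 drawn joint splits gave 250 genes or more, with 504 the highest other. All 6 were among the 11 splits that kept shHuR and shluc 1 to 3 apart and so kept the shHuR effect, and the highest of the others was 4. Splits that hold a real effect are no reference for chance, so this count neither excludes chance nor speaks for it.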

How the results depend on the processing

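The choice of control arrays changed the results most. With all 6 shluc arrays pooled, as first planned, 433 genes passed for shHuR, 0 for shCRABP2 (2172 at an unadjusted p under 0.05, limma) and 7117 for shHuR against shCRABP2, CRABP2 was at -0.69 and short of the threshold, and the correlation of the 2 knockdowns turned to -0.44. These fits set arrays of separately normalized sets side by side. With the shluc number sets as a random block the counts were 0, 0 and 0 and CRABP2 was at -0.69. In that fit each knockdown was a block of its own, apart from the shluc arrays of its set. The correlation within blocks was 0.88. The fit therefore could not compare a knockdown within its set, and its counts do not speak against the calls within sets. With shluc 1 to 3 as the control, 11515 genes passed for shCRABP2 and 11655 for the difference, and CRABP2 was at -0.17 and short of the threshold. With shluc 4 to 6, 11739 passed for shHuR and 11740 for the difference. With the controls exchanged the correlation turned to -0.81. After quantile normalization the other set's controls gave 8355 and 8303, with CRABP2 at -0.70 and past the threshold (adjusted p = 3.88e-05; added after seeing the data). Of single genes, only CRABP2 was taken through these cross-set fits, and no list was.

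Within the sets, a fit of only the 2 groups gave 764 for shHuR, 21 for shCRABP2 and, across the sets, 11819 for the difference. With trend and robust eBayes, 170 passed for shCRABP2 and 482 for the difference. A further quantile normalization gave 122 for shCRABP2, 49 up and 73 down against 21 and 53. Array weights gave 139 and 399. Without the dimmer genes (those below the median mean signal), 227 and 592 passed, the correlation was 0.39, and 6191 differed between the shluc sets. In that fit fewer genes were tested and the spread was also estimated anew from the brighter genes, and the shares of these 2 changes were not told apart. Over all probe sets (added after seeing the data) 14 and 63 passed. At a fold of at least 1.5, 354 passed for shHuR and 29 for shCRABP2. The correlation was 0.14 without the cell cycle lists and every gene past the threshold (added after seeing the data). For gene lists, an estimated correlation left 0 of 6 past the threshold for shCRABP2 and 1 of 2 for the difference, and fry placed 1 for shCRABP2. Except where construction is named, the cause was not tested.

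Leaving out 1 array lowered the 1408 genes for shHuR by 174 to 435, to 973 at the least, and gave 7 to 49 genes for shCRABP2 and 52 to 244 for the difference, CRABP2 from -1.32 to -1.07, the correlation from 0.23 to 0.29, 10536 to 11014 genes between the shluc sets, and 2 to 5, 4 to 6 and 2 to 4 lists for shHuR, shCRABP2 and the difference.

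With the replicate block, fitted for shHuR with shluc 1 to 3, 1341 genes passed against 1408, 3 lists as before, and of the named genes BIRC2 alone lost its call. Arrays with the same number did not deviate together (correlations 0.059, -0.062 and -0.096, against up to 0.17 between unlike numbers). These values give no sign of a pairing by number, but they cannot rule out a shared culture or day. For shCRABP2 no paired analysis was possible because its numbers are shared with shluc arrays of the other set.

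Of the alternatives for named genes, 2345 kept direction and side of the threshold, 186 lost the threshold, 66 gained it and 6 uncalled values changed sign. For lists these counts were 911, 25, 9 and 52. No called gene or list within a set changed sign. The number of arrays, and dim signals kept in the fit, limit the precision.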

Other observations

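The gene families below were picked and tested only after the data were seen.

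Of 20 families picked by symbol prefix, 17 had at least 3 measured genes. The beta protocadherins, cell adhesion genes in one cluster, were higher in shHuR for 17 of 19, and 3 passed the threshold, PCDHB6 at a log2 change of 0.99, PCDHB8 at 0.74 and PCDHB10 at 0.34. In shCRABP2 none of the 19 passed, with PCDHB6 at -0.20 and PCDHB8 at -0.09. Camera at its preset correlation placed the family past the threshold in shHuR (adjusted p = 0.00019 over the families tested), and a rise of the family as a set may be proposed as a hypothesis, but with an estimated correlation the adjusted p was 0.51, so it was not borne out. Kinesins, the motors of the mitotic spindle among them, were past the threshold in camera in both knockdowns, with 13 of 40 fallen in shHuR and 1 in shCRABP2 (adjusted p = 0.0031 and 0.0058), and with an estimated correlation in neither (adjusted p = 0.79 and 0.98). The SNAR RNAs, near-identical noncoding RNAs, shifted down in shCRABP2 in camera with 0 of 8 past the threshold (adjusted p = 0.0058, and 0.84 with an estimated correlation).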
